A study of Mus musculus with 12 samples.

How the data were processed

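Total RNA of cultured mouse podocytes was extracted with Trizol and column purification with DNase, amplified to biotin-labelled cRNA and hybridised to Illumina mouse arrays, per the labels' protocols. The 12 arrays fall into 4 groups of 3: control, DZNep, high glucose, and high glucose plus DZNep, each after 48 h. Groups and replicate numbers were taken from the labels. Probe signals were deposited as linear intensity values, not normalized, per the file headers. A detection p-value for each probe and array was deposited beside them, per the file headers. GenomeStudio is named as a tool, per the submitters' processing notes, and its version is not given in the sources used here. A further table of processed intensity values from the authors was a linear function of the raw signal on each array (factor 0.832 to 1.12, largest residual 0.011). Its mean was 568.254 on every array, so an offset had been subtracted and each array scaled to a common mean. Its array medians were 9.97 to 11.39, and 32.6% to 36% of its values lay below 0. What the offset was meant to remove stays unknown.

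Intensities were background-corrected from the detection p-values (normexp, offset 16), quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Folds are therefore on the log2(background-corrected intensity + 16) scale and understate changes of dim genes. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none; 34807 gene IDs matched the RefSeq table of assembly GRCm38.p6, from which only names and gene order were used, since the array files name no build. Probes with a detection p under 0.05 on at least 3 arrays were kept (19273, of which 16311 had 1 symbol). The probe with the highest mean over all arrays stood for each of 10258 genes, and 4071 genes had more than 1 detected probe. Another probe of the gene passed in the opposite direction for 91 of 1510 changed genes with several probes for DZNep against control, 0 of 12 for high glucose against control and 34 of 1028 for DZNep in high glucose. Another probe had under 0.5 times the change or the opposite sign for 775, 5 and 490 of these genes, so that many calls do not hold at every probe. Values of other probes come from the same model fitted across all detected probes with 1 symbol, with p-values adjusted over these probes. A gene detected on no array of a group was given as at least N-fold, from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among detected probes and the gene's own.

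A linear model of the 4 group means over the 12 arrays was fitted with lmFit and eBayes of limma, with 11.32 residual degrees of freedom including the prior. The p-values were adjusted by the Benjamini-Hochberg method within each of 8 comparisons, at an adjusted p under 0.05. SE is the standard error from that fit. Sets of at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The 29 lists were podocyte genes, PRC2 subunits, developmental regulators bound by PRC2, HOX genes, other histone methyltransferases and demethylases, methionine cycle and polyamines, thioredoxin system, NRF2 targets, NADPH oxidase and superoxide enzymes, MondoA and ChREBP targets, glycolysis and glucose transport, cholesterol synthesis, cell cycle, p53 targets, matrix and fibrosis, interferon-stimulated genes, inflammatory cytokines and chemokines, unfolded protein and integrated stress response, imprinted genes, germline genes, Wnt pathway, apoptosis, lysosome and autophagy, respiratory chain, and markers of mesangial, endothelial, tubular, parietal and leukocyte cells.

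Groups, models, the 29 lists, the alternatives and the rule for named genes were chosen before the data were examined, except that the alternative with a stricter filter and without control replicate 3 was added afterwards. The rule names Ezh2, Ezh1, Eed, Suz12, Ahcy, Txnip, Pax6, Nphs1, Synpo and Wt1 always, and an item that is not reported here. It also names up to 8 genes in each direction in the 3 main comparisons and up to 4 in the others, taken by size among genes that passed with no overlap between arrays, leaving out gene models without a standard symbol. From each list it names up to 4 members that passed, or up to 2 with the smallest p where none did.

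The scripts were tested on simulated data with 200 of 10258 genes changed. For DZNep against control 61% of changes of 0.5 and 94% of changes of 1 (log2) were recovered, for high glucose against control 66% and 98%, and for the interaction 27% and 86%. Of the genes called, 14 of 169, 4 of 168 and 11 of 124 were unchanged ones in that order, so that the first and the last share lay above the nominal 5%. A list shifted by -0.3 was called in 20 of 20 simulated sets, in which 3 calls of other lists were also made. A further 20 sets with no change gave 2 calls of a list. The simulated noise was independent between genes, so these sets cannot show how the list test behaves where members are correlated. Alternatives were other background correction and normalization, the authors' values, other filters and probe rules, the replicate number as a block, other variance models and array weights, only the arrays compared, a fold threshold, other set tests, and leaving out each array. Figures were drawn with matplotlib 3.10.9.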

Results

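Cultured mouse podocytes, the epithelial cells that wrap the glomerular capillaries of the kidney, were profiled on Illumina mouse expression arrays after 48 h in 4 conditions. The conditions were no addition (control), DZNep, high glucose, and high glucose plus DZNep, with 3 arrays each. DZNep is named in the series as an inhibitor of EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2), and is known to block the hydrolase of S-adenosylhomocysteine. Between 38.4% and 41.3% of the 45281 probes were detected per array, and the median raw signal lay between 133 and 151. The 12 arrays correlated at 0.979 to 0.997. The first principal component, with 46.9% of the variance, separated the arrays with DZNep from those without it, and control replicate 3 stood apart on the second (13.5% of the variance) at -20.5. Expression was compared for 10258 genes. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

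The first comparison asked what DZNep did at normal glucose. Ezh2 itself fell by 0.89 on the log2 scale (SE 0.094, n = 3 per group, adjusted p = 7.28e-05), to a fold of 0.54. At its other detected probe Ezh2 changed by -0.569 (unadjusted p = 0.026 in a limma fit of the detected Ezh2 probes alone). The strongest increases were in Hba-a1, an alpha-globin gene (log2 change 2.59, SE 0.097, adjusted p = 1.45e-07), and C2cd4a (2.53, SE 0.103, adjusted p = 1.85e-07). Fgd3, a guanine nucleotide exchange factor, rose by 1.86, Igfbp2, an insulin-like growth factor binding protein, by 1.85, Atg9b, an autophagy gene, by 1.80, and Tnfrsf18, a TNF receptor family member, by 1.78. Arvcf, a catenin, and Slc37a2 rose by 1.75 and 1.72. Tgfbi, a secreted matrix protein induced by TGF-beta, was not well above background on the DZNep arrays and was at least 2.95-fold lower (adjusted p = 5.45e-07). Adgra1, an adhesion receptor, fell by 1.66 (SE 0.081, adjusted p = 4.37e-07).

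In all, 3473 genes changed with DZNep (33.9%), 2082 higher and 1391 lower, and 158 of them changed at least 2-fold. In 3365 of them every array of 1 group lay beyond every array of the other, which held for 44.6% of all genes against 10% by chance. With arrays centred on their medians the split was 969 higher and 1273 lower. Adss, Hnrnpa2b1, Rbbp7, Hif1a, Gulp1 and Ddx5 fell (-1.78, -1.74, -1.73, -1.73, -1.68 and -1.60), with control SDs from 0.50 (Hif1a) to 0.76 (Rbbp7). Each of these calls held when any single array was left out. High glucose set against the same controls gave -1.03, -0.92, -1.11, -0.83, -1.03 and -1.18 for these genes, none of which passed (adjusted p from 0.109 to 0.202). DZNep in high glucose gave -0.42, -0.485, -0.11, -0.34, -0.16 and -0.01, none of which passed either.

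Among 9 measured PRC2 subunits, Ezh2 and the histone-binding subunit Rbbp7 (-1.73, SE 0.36, adjusted p = 0.00403) fell and 7 did not pass. Adjusted over the list alone, 4 fell. Suz12 changed by -0.23 (adjusted p = 0.0544), Ezh1 by -0.16 (adjusted p = 0.503) and Eed by 0.33 (adjusted p = 0.233). Of 9 measured developmental regulators that PRC2 binds in stem cells, 0 changed, and 0 when adjusted over the list alone. Of 25 measured HOX genes, 2 rose and 6 fell, with the same counts adjusted over the list alone: Hoxd9 rose by 0.50 (adjusted p = 0.00217), while Hoxa2 (-0.74, adjusted p = 0.00821) and Hoxa5 (-0.49, adjusted p = 0.000378) fell. Of 27 other histone methyltransferases and demethylases, 4 rose and 7 fell, also adjusted over the list alone (2 and 6 without control replicate 3). Nsd1 (-0.71, adjusted p = 0.00196) and Kdm3a (-0.64, adjusted p = 0.000516) fell. Pax6 was detected on 0 of 12 arrays by its 2 probes, and Wt1 was not analysed here.

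Interferon-stimulated genes rose with DZNep: 17 of 26 measured were higher, 3 lower and 6 did not pass, with the same counts adjusted over the list alone and a list median of 0.33. Ifit3 rose by 1.63 (SE 0.109, adjusted p = 3.69e-06), Dhx58, a viral RNA sensor, by 1.20, Igtp by 0.88 and Isg15 by 0.80. The list passed camera (adjusted p = 0.00237; adjusted p = 0.0852 with an estimated correlation). Without control replicate 3, 12 were higher and 0 lower. The same arrays showed Laptm5, a leukocyte marker not well above background in control, at least 1.72-fold higher (adjusted p = 0.00193), while of 6 measured leukocyte markers 2 rose and 1 fell (3 and 1 adjusted over the list alone; 1 and 0 without control replicate 3).

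Glycolysis genes fell: of 17 measured genes of glycolysis and glucose transport, 0 rose and 7 fell, also adjusted over the list alone, with a median of -0.24 (-0.358 in the authors' values). The examples were Pdk1, which inhibits pyruvate dehydrogenase (-0.81, SE 0.133, adjusted p = 0.00106), aldolase Aldoa (-0.55), Pgk1 (-0.54) and lactate dehydrogenase Ldha (-0.47, adjusted p = 0.00265). The list passed camera (adjusted p = 0.00237; adjusted p = 0.319 with an estimated correlation), and the same number of genes fell without control replicate 3. Of 13 measured targets of the glucose-sensing factors MondoA and ChREBP, 3 rose and 2 fell, also adjusted over the list alone (2 and 2 without control replicate 3). Among these Txnip, the thioredoxin-binding protein induced by glucose, rose by 0.31 (SE 0.061, adjusted p = 0.00285), and transketolase Tkt fell by 0.55. Of 24 respiratory chain genes, 2 rose and 4 fell (0 and 2 adjusted over the list alone or without control replicate 3), and of 18 cholesterol synthesis genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), with mevalonate kinase Mvk higher by 1.36.

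Of 19 measured p53 targets, 8 rose and 2 fell, also adjusted over the list alone (7 and 1 without control replicate 3). Mdm2, which ubiquitinates p53, rose by 0.82 (adjusted p = 6.72e-05), Plk3 by 0.77 and the exonuclease Aen by 0.70, while Sesn1 fell by 0.49. The list did not pass camera (adjusted p = 0.323). Of 33 cell cycle genes, 6 rose and 4 fell (3 and 2 adjusted over the list alone; 3 and 1 without control replicate 3), with Rrm2 higher by 0.50 and Foxm1 by 0.49. Of 19 apoptosis genes, 4 rose and 1 fell (3 and 1 adjusted over the list alone), the latter the pro-apoptotic Bmf (-1.27, adjusted p = 7.14e-05). Of 26 genes of the unfolded protein and integrated stress response, 8 rose and 4 fell, also adjusted over the list alone. Atf3 rose by 0.63 and the lipoprotein receptor Vldlr fell by 0.83. Of 24 lysosome and autophagy genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone; 3 and 2 without control replicate 3), with Ctsa higher by 0.86.

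Redox genes moved both ways. Of 14 thioredoxin system genes, 3 rose and 4 fell, also adjusted over the list alone (3 and 1 without control replicate 3), and Txnrd3 rose by 0.83 (adjusted p = 2.91e-05). Of 22 NRF2 antioxidant targets, 2 rose and 5 fell, also adjusted over the list alone (1 and 4 without control replicate 3); sulfiredoxin Srxn1 fell by 0.80 (adjusted p = 2.2e-05). Of 10 NADPH oxidase and superoxide genes, 1 rose and 2 fell, also adjusted over the list alone, and catalase Cat fell by 0.33. Of 13 methionine cycle and polyamine genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone; 1 and 0 without control replicate 3), and the serine hydroxymethyltransferase Shmt2 rose by 0.63 (adjusted p = 0.000335). Ahcy, the hydrolase that DZNep is known to block, rose by 0.35 (SE 0.113, adjusted p = 0.0314), and by 0.493 at its other detected probe (adjusted p = 0.033). Its call ended without control replicates 2 or 3 (0.222 without the latter) or any 1 DZNep array, with adjusted p up to 0.184 over the settings listed.

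Of 28 measured podocyte genes, 9 rose and 3 fell (10 and 4 adjusted over the list alone; 5 and 2 without control replicate 3). Col4a3, a chain of the glomerular basement membrane, fell by 0.98 (adjusted p = 0.00573) and integrin Itgb1 changed likewise (-0.83, adjusted p = 0.000898). Nphs1, which encodes nephrin of the slit diaphragm, rose by 0.22 (SE 0.064, adjusted p = 0.0205); that call ended without control replicates 1 or 2 or DZNep replicate 2, with adjusted p up to 0.185 over the settings listed. Synpo, an actin-associated podocyte protein, changed by 0.13 (adjusted p = 0.307) at the probe used and fell by 0.47 at its other detected probe (adjusted p = 0.0241), so that its direction is not settled. Of 27 matrix and fibrosis genes, 6 rose and 7 fell, also adjusted over the list alone: Ccn1 and Ccn2 rose by 1.04 and 0.93, while the crosslinking enzyme Loxl1 fell by 1.29 (adjusted p = 5.75e-07). Of 15 inflammatory cytokines and chemokines, 5 rose and 2 fell (5 and 3 adjusted over the list alone; 5 and 1 without control replicate 3), with Icam1 and Cxcl12 higher by 0.87 and 0.83 and Vcam1 lower (-0.79). Of 13 imprinted genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Peg10 higher by 0.83 and Gnas lower (-0.85). Of 5 germline genes, 2 rose (2 and 1 lower adjusted over the list alone), and the homeobox gene Rhox5 rose by 1.13 (adjusted p = 8.69e-05). Of 13 Wnt pathway genes, 2 rose and 1 fell, also adjusted over the list alone (1 and 1 without control replicate 3), with Wnt5a higher by 0.51.

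Markers of other kidney cell types were measured on the same arrays. Of 5 endothelial markers 3 rose and 0 fell, with Esam higher by 0.98 (adjusted p = 0.000791) and Eng by 0.80 (adjusted p = 0.0108). Of 7 mesangial, smooth muscle and fibroblast markers 2 rose and 0 fell, with Gata3 higher by 1.13 and Pdgfrb by 0.69. Of 7 tubular markers 1 rose (Cdh1, 0.62) and 1 fell (Cdh16, -0.34), and of 8 parietal markers 1 rose and 1 fell (0 and 1 without control replicate 3). Each of these counts was the same adjusted over the list alone. Apart from the interferon and glycolysis lists, none of the 29 lists passed camera in this comparison. Other detected probes of some named genes moved less or the other way. At their other probe Ifit3 changed by 0.30 (adjusted p = 0.469), Hnrnpa2b1 by -0.40, Itgb1 by -0.17, Nsd1 by -0.27, Hoxd9 by 0.23 and Shmt2 by -0.25, and none of these passed. The 4 other Ctsa probes lay from -0.53 to 0.34 and both other Cxcl12 probes near 0 (-0.015 and 0.075), without passing. Of 5 other Gnas probes 3 lay from -0.09 to 0.10 and did not pass. Of the other probes of Rbbp7 (3), Dhx58 (2), Rrm2 (2) and Wnt5a (2), 1 each did not pass, at -0.06, 0.32, -0.05 and 0.09; in high glucose that Rrm2 probe fell by 0.44 with DZNep (adjusted p = 0.03), against a rise of 0.49 at the probe used. The other probes of Arvcf (0.665) and Atg9b (0.59) and 1 of 2 of Ccn1 (0.52) passed with a smaller rise. For 9 of the lists that did not pass, among them the matrix (median 0.05, mean -0.05) and inflammatory (median -0.05, mean 0.10) lists, the median, the mean and the camera direction differed in sign.

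**Figure D1:**
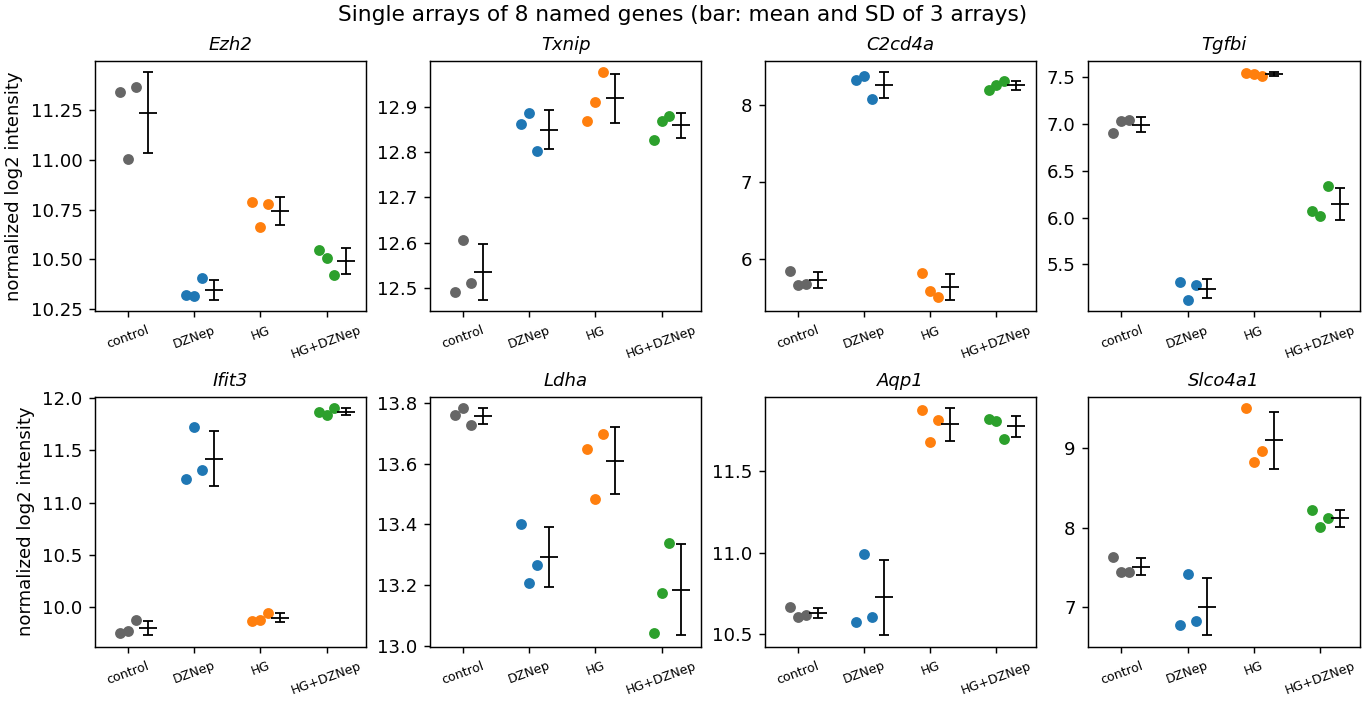
Normalized log2 intensity (vertical axis) of 8 named genes on each of the 12 arrays (points; 3 per group), with the mean and SD of each group as a bar; HG stands for high glucose. Values are those of the probe used for each gene. Ezh2 lay above its level on all other arrays in the control group, C2cd4a and Ifit3 were higher on every array with DZNep, and Aqp1 was higher on every array with high glucose.

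The next comparison asked what high glucose did without DZNep. Prss35, a serine protease family member not well above background in control, was at least 3.57-fold higher (adjusted p = 0.00651). Slco4a1, an organic anion transporter, rose by 1.59 (SE 0.189, n = 3, adjusted p = 0.00651), the water channel Aqp1 by 1.16 (SE 0.104, adjusted p = 0.0019), the methyltransferase Inmt by 0.92 (SE 0.11, adjusted p = 0.00651) and the growth factor Fgf10 by 0.67 (adjusted p = 0.00625). Ncapg2, a condensin subunit, fell by 0.77 (SE 0.083, adjusted p = 0.00625), while its other probe changed by -0.29 (adjusted p = 0.337). Without high glucose replicate 3 Inmt had an adjusted p of 0.05 and no longer passed (0.138 at most over the settings listed). The calls of the other 5 genes held when any single array was left out, and Prss35 did not pass in the authors' values. Of 18 named genes called in this comparison, 1 was called under all alternatives.

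In all, 29 genes changed with high glucose, 21 higher and 8 lower, and 1904 had an unadjusted p under 0.05. In all 29 the arrays of the groups did not overlap, as in 21% of all genes. The count was 155 higher and 185 lower with quantile normalization and no background correction, and 7 higher and 1 lower in the authors' values. It was 70 without control replicate 1 and 58 without DZNep replicate 1. It was 10 without control replicate 3 or high glucose plus DZNep replicate 1, 11 without DZNep replicate 2, and 7 and 12 without high glucose plus DZNep replicates 2 and 3. Without high glucose replicates 1, 2 and 3 it was 7, 6 and 5.

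Txnip rose by 0.38 (SE 0.061, adjusted p = 0.0387). That call ended without control replicate 3, without DZNep replicate 2, and without any 1 of the arrays with high glucose, with estimates from 0.36 to 0.42 and adjusted p up to 0.187 over the settings listed. Ezh2 changed by -0.49 (SE 0.094, adjusted p = 0.0605), Suz12 by -0.14 (adjusted p = 0.412), Ezh1 by -0.12 (adjusted p = 0.756), Eed by -0.11 (adjusted p = 0.81), Ahcy by 0.09 (adjusted p = 0.718), Nphs1 by 0.27 (adjusted p = 0.087) and Synpo by -0.02 (adjusted p = 0.944). At its other detected probe Ezh2 changed by -0.139 (unadjusted p = 0.54 in a limma fit of the detected Ezh2 probes alone). Of the 29 lists, 25 held 0 changed genes. The exceptions held 1 higher gene each: Txnip in the thioredoxin and the MondoA and ChREBP lists, Tgfbi (0.54, adjusted p = 0.0423) in the matrix list and Aqp1 in the tubular list, which had 2 higher adjusted over the list alone. Adjusted over the list alone, PRC2 subunits showed 1 higher and 2 lower, other histone enzymes 0 and 2, and interferon-stimulated genes 1 and 2. The cholesterol, matrix and parietal lists showed 1 and 1, the podocyte, NRF2 and leukocyte lists 1 and 0, and the p53, imprinted and respiratory chain lists 0 and 1. Tgfbi lost its call without any single array other than DZNep replicate 1 or high glucose plus DZNep replicate 3, with estimates from 0.29 to 0.56 and adjusted p up to 0.15 over the settings listed. The cell cycle list (33 genes, median -0.08) and the germline list (5 genes, median -0.26) were lower by camera (adjusted p = 0.0481 for each; adjusted p = 0.467 and 0.405 with an estimated correlation), with 0 members changed. The cell cycle median was -0.0388 and -0.0453 without control replicates 1 and 2 and -0.122 with the mean of all detected probes. The germline median was -0.13 without control replicate 2, -0.0217 without a filter on dim probes, -0.079 with quantile normalization and no background correction and -0.482 in the authors' values. Neither passed without control replicates 2 or 3, DZNep replicate 1, high glucose plus DZNep replicate 1 or any 1 high glucose array. Without control replicate 1 or DZNep replicate 2 the cell cycle list alone did not pass (adjusted p = 0.0985 and 0.0539). Over the settings listed with the preset correlation the adjusted p reached 0.237 for the cell cycle and 0.775 for the germline list. Adjusted over the list alone, 0 cell cycle genes and 1 germline gene fell. Tdrkh, a germline gene, changed by -0.54 (adjusted p = 0.0655) and Top2a, a cell cycle topoisomerase, by -0.57 (adjusted p = 0.087). At other detected probes Tdrkh changed by -0.306 and Top2a by -0.164 and -0.086.

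The comparison of DZNep within high glucose asked which DZNep responses were present when glucose was raised. C2cd4a rose by 2.62 (SE 0.103, n = 3, adjusted p = 2.51e-07), Fgd3 by 2.04, Ifit3 by 1.98 (adjusted p = 1.26e-06) and the transporter Slc25a2 by 1.62. Arvcf rose by 1.55, Hba-a1 by 1.55, endothelin Edn1 by 1.53 (adjusted p = 4.18e-06) and Sprr2g, a keratinocyte envelope gene, by 1.47. The receptor Mrgprf fell by 2.06 (adjusted p = 9.9e-06), as did Adgra1 (-1.82), Tmem44 (-1.63), Pdgfrl (-1.63), Vit (-1.56), Gnaz (-1.56) and Tmem25 (-1.55). The ecto-nucleotidase Nt5e was not well above background with DZNep and was at least 2.31-fold lower (adjusted p = 5.17e-05). The other Tmem44 probe changed by -0.02 (adjusted p = 0.969), so that this fall rests on 1 of 2 probes. The other probes of Fgd3 (0.715) and Arvcf (0.51) passed with a smaller rise. Ezh2 changed by -0.25 (SE 0.094, adjusted p = 0.0721), Txnip by -0.06 (adjusted p = 0.53) and Nphs1 by 0.12 (adjusted p = 0.189). At its other detected probe Ezh2 changed by -0.468 (unadjusted p = 0.0577 in a limma fit of the detected Ezh2 probes alone). Ahcy changed by 0.14 (adjusted p = 0.397), and by 0.427 at its other detected probe (adjusted p = 0.0782). Suz12 changed by -0.04 (adjusted p = 0.765), Ezh1 by 0.07 (adjusted p = 0.82) and Eed by 0.28 (adjusted p = 0.341), and the Synpo estimate was 0 (adjusted p = 1).

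In all 2487 genes changed, 1268 higher and 1219 lower. Of these, 2470 had no overlap between the arrays, which held for 44.4% of all genes against 10% by chance. The split was 1509 higher and 924 lower in the authors' values. The count was 1639 without high glucose plus DZNep replicate 2 and 1657 without replicate 3 of that group.

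Of 26 interferon-stimulated genes, 12 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.25; Isg15 rose by 0.88 and Igtp by 0.72. Without a filter on dim probes the median of this list was 0.0443, and with quantile normalization and no background correction 0.163. Of 17 genes of glycolysis and glucose transport, 1 rose and 9 fell (1 and 11 adjusted over the list alone), with a median of -0.26; Pdk1 (-0.97), Aldoa (-0.51) and Pgk1 (-0.48) fell. Both lists passed camera (adjusted p = 0.000874 for each; adjusted p = 0.0592 and 0.175 with an estimated correlation). Of 19 p53 targets, 9 rose and 2 fell, also adjusted over the list alone, with Mdm2 higher by 0.71, Aen by 0.69 and the death receptor Fas by 0.69; of 2 other Aen probes 1 changed by 0.01 (adjusted p = 0.987). This list passed camera too (adjusted p = 0.00787; adjusted p = 0.0959 with an estimated correlation).

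HOX genes showed 2 higher and 6 lower of 25, also adjusted over the list alone, with Hoxa5 (-0.43) and Hoxd8 (-0.49) lower. Of 9 PRC2 subunits, 0 rose and 1 fell, also adjusted over the list alone, and of 9 developmental regulators bound by PRC2 0 rose and 1 fell (0 adjusted over the list alone). Matrix genes showed 6 higher and 6 lower of 27 (7 and 6 adjusted over the list alone), with Ccn2 higher by 0.82 and Loxl1 lower (-1.39). Of 28 podocyte genes 5 rose and 1 fell (3 and 0 adjusted over the list alone), with Arhgap24, a podocyte GTPase regulator, higher by 0.39 (adjusted p = 0.00356) and at 0.045 by its other probe (adjusted p = 0.914). Endothelial markers showed 3 higher and 0 lower of 5, with Ehd3 higher by 0.52 (adjusted p = 0.00232), and mesangial markers 2 higher of 7, with Gata3 higher by 0.91. Leukocyte markers showed 1 higher and 0 lower of 6, the higher one Csf1r (0.50, adjusted p = 0.0329). Each of these 3 counts was the same adjusted over the list alone.

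**Figure D2:**
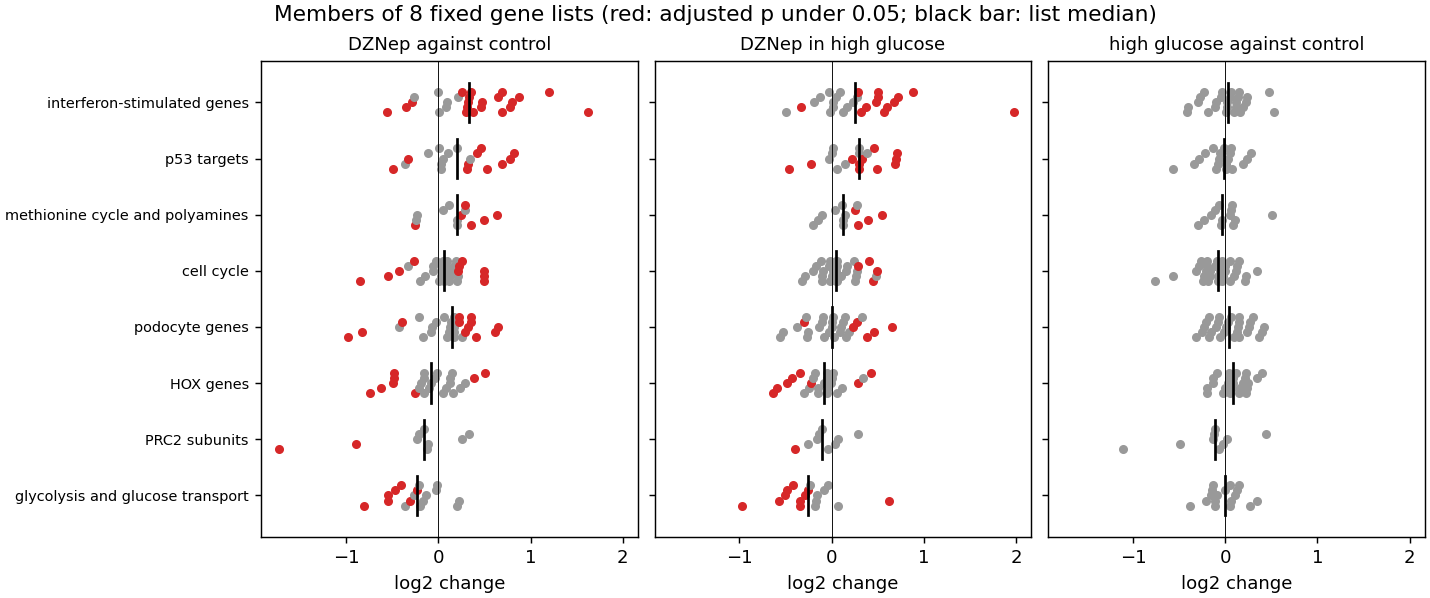
Log2 change (horizontal axis) of the measured members of 8 fixed gene lists in 3 comparisons; each point is a gene, red where the adjusted p was under 0.05, and the black bar is the list median. The interferon median lay at 0.33 and 0.25 and the glycolysis median at -0.24 and -0.26 in the DZNep comparisons.

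The DZNep responses at the 2 glucose levels, which share no array, were then set against each other. Across the 10258 genes the log2 changes correlated at r = 0.663 (rho = 0.601), where genes are not independent replicates. Of the genes that changed in both, 1617 changed in the same direction and 21 in opposite directions. Independent lists would have shared 257 risen genes against 943 observed, and 165 fallen genes against 674 observed. The difference of the DZNep effects passed the test for 5 genes. Bod1l differed by 1.61 (SE 0.212), from -0.90 at normal glucose to 0.71 in high glucose. Akap9, a centrosomal scaffold, differed by 0.99 (from -0.31 to 0.68) and Ncapg2 by 0.82 (from -0.37 to 0.46; 0.215 at its other probe, adjusted p = 0.639). Hba-a1 differed by -1.05 (from 2.59 to 1.55) and the matrix gene Matn4 by -0.75 (from 1.00 to 0.25). All 5 had an adjusted p of 0.0383. The difference for Ezh2 was 0.64 (adjusted p = 0.097) and for Txnip -0.37 (adjusted p = 0.109), and for Ahcy it was -0.21 (adjusted p = 0.529), so for none of the 3 was a difference shown. At the other detected Ezh2 probe the DZNep effects lay closer together, at -0.569 without and -0.468 with high glucose. Suz12, Ezh1, Eed, Nphs1 and Synpo did not pass either (adjusted p from 0.454 to 0.953).

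The count of 5 was 13 and 12 genes without control replicates 1 and 2, 1 without high glucose replicate 1, and 0 without any other single array. At an unadjusted p under 0.05, 1618 genes differed. Centring on medians gave 3 higher and 0 lower.

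**Figure D3:**
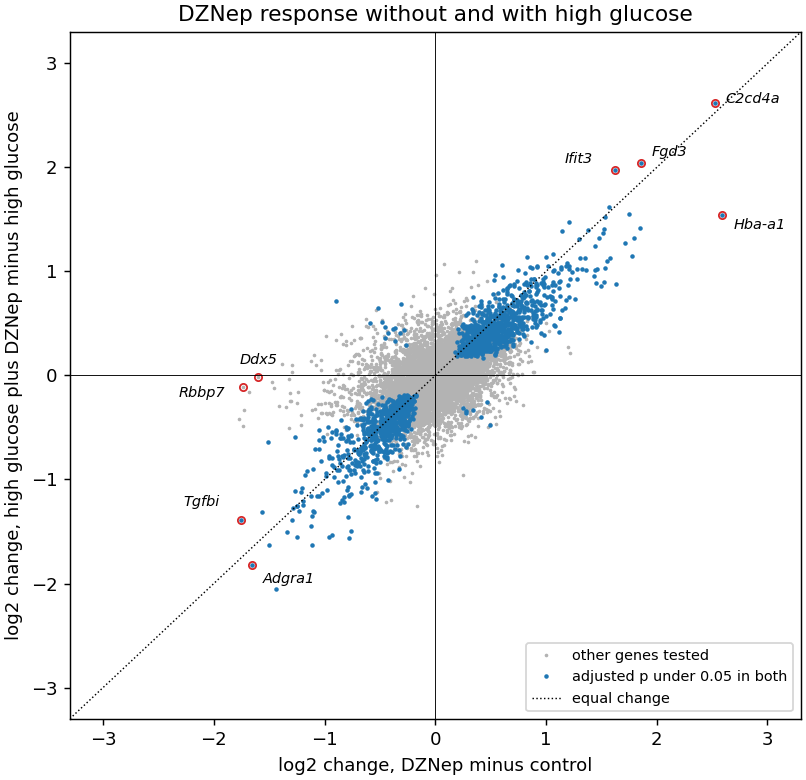
Log2 change with DZNep at normal glucose (horizontal axis) against that in high glucose (vertical axis) for the 10258 genes tested; blue points passed in both comparisons, red circles mark named genes and the dotted line marks equal change. C2cd4a lies near the line at 2.53 and 2.62, Hba-a1 lies under it at 2.59 and 1.55, and Rbbp7 (-1.73 and -0.11) and Ddx5 (-1.60 and -0.01) lie left of the cloud.

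High glucose in the presence of DZNep changed 6 genes, 3 higher and 3 lower, and 1059 had an unadjusted p under 0.05. Aqp1 rose by 1.05 (SE 0.104, n = 3, adjusted p = 0.00268) and Inmt by 0.91 (adjusted p = 0.0135). Tgfbi, not well above background with DZNep alone, was at least 1.64-fold higher (adjusted p = 0.00268). Hba-a1 (-0.76, adjusted p = 0.0183) and Ms4a10 (-0.63, adjusted p = 0.0371) were lower, and Ctsw, a cathepsin not well above background with both treatments, was at least 1.35-fold lower (adjusted p = 0.0345). Nphs1 changed by 0.17 (adjusted p = 0.394), Ezh2 by 0.14 (adjusted p = 0.629), Ahcy by -0.12 (adjusted p = 0.75) and Txnip by 0.01 (adjusted p = 0.971), and Suz12, Ezh1, Eed and Synpo did not pass either (adjusted p from 0.611 to 0.866). The calls of Aqp1 and Tgfbi held when any single array was left out. Those of Inmt and Hba-a1 ended without DZNep replicates 1 or 3 or high glucose plus DZNep replicate 1, and also without replicate 2 (Inmt) or 3 (Hba-a1) of the latter group, with adjusted p up to 0.0736 and 0.117 over the settings listed. Those of Ctsw and Ms4a10 ended without any single array other than control replicates 2 or 3, high glucose replicate 1 or, for Ctsw, high glucose plus DZNep replicate 2, with adjusted p up to 0.159 and 0.189. None of the 29 lists passed camera here, while 2 passed fry, and 1 passed camera without DZNep replicate 1. The glucose effects with and without DZNep correlated across genes at r = -0.0963, and 3 genes changed in both, all upward. The count was 16 without control replicate 3 and 10 without high glucose replicate 1. It was 2 without DZNep replicate 1, DZNep replicate 3 or high glucose plus DZNep replicate 1, 3 without replicate 3 of that group, and 4 without high glucose replicate 2.

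Averaged over DZNep, high glucose changed 24 genes, 20 higher and 4 lower, led by Prss35 (adjusted p = 0.00373), Slco4a1 (1.35), Aqp1 (1.11) and Inmt (0.92). Nphs1 changed by 0.22 (adjusted p = 0.0945), Txnip by 0.20 (adjusted p = 0.107), Ezh2 by -0.17 (adjusted p = 0.311) and Ahcy by -0.02 (adjusted p = 0.959), and Suz12, Ezh1, Eed and Synpo did not pass either (adjusted p from 0.648 to 0.993). Camera placed the tubular (adjusted p = 0.0443) and matrix (0.0419) lists higher and the germline (0.00302) and cell cycle (0.0144) lists lower. The 7 measured tubular genes include Aqp1 (1.11), against a list median of 0.044, and the list was not tested without Aqp1. With an estimated correlation the adjusted p was 0.226 for the tubular, matrix and cell cycle lists and 0.121 for the germline list. The germline median was -0.295, -0.0195 without a filter on dim probes and -0.0883 with quantile normalization and no background correction. The tubular and matrix medians were 0.044 and 0.0589, and 0.00293 and 0.0221 without that filter. With arrays centred on their medians the tubular median was 0.0662, and with quantile normalization and no background correction the matrix median was 0.0375. The tubular median was 0.00587 and 0.084 without high glucose replicates 3 and 1, and 0.13 and 0.0742 without DZNep replicates 1 and 2. The matrix median was 0.0912 and 0.0309 without control replicates 2 and 3, and 0.0385 without high glucose plus DZNep replicate 3. The number of lists was 1 without DZNep replicate 3 and 2 without control replicates 2 or 3, high glucose plus DZNep replicates 2 or 3 or high glucose replicate 3. The gene count fell to 6 without high glucose replicate 3 and 7 without control replicate 2 or high glucose plus DZNep replicates 1 or 2. It was 9 without DZNep replicate 3 or high glucose replicate 2, 13 without DZNep replicate 1 or high glucose plus DZNep replicate 3, and 15 without high glucose replicate 1.

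DZNep averaged over glucose changed 4295 genes, 2404 higher and 1891 lower, with C2cd4a higher by 2.57, Hba-a1 by 2.07 and Fgd3 by 1.95, and Mrgprf (-1.75) and Adgra1 (-1.74) lower. Ezh2 fell by 0.57 (adjusted p = 5.9e-05), and Ahcy rose by 0.25 (SE 0.08, adjusted p = 0.0265), Nphs1 by 0.17 (adjusted p = 0.0102) and Txnip by 0.13 (adjusted p = 0.0346). The Ahcy call ended without high glucose replicate 3 or high glucose plus DZNep replicates 1 or 2. The Txnip call ended without any single array other than control replicate 2, DZNep replicate 3, high glucose replicate 3 or high glucose plus DZNep replicate 1. Over the settings listed the adjusted p reached 0.117 for Ahcy, 0.0932 for Nphs1 and 0.292 for Txnip. Suz12, Ezh1, Eed and Synpo did not pass (adjusted p from 0.0877 to 0.788), while the other Synpo probe fell by 0.37 (adjusted p = 0.0119). The other Fgd3 probe rose by 0.91. Against control, the 2 treatments together changed 3090 genes, 1759 higher and 1331 lower. C2cd4a rose by 2.52, Fgd3 by 2.35 and Ifit3 by 2.08, Rgcc, a cell cycle regulator, fell by 1.59, and Ezh2 (-0.75, adjusted p = 0.00025) fell. Nphs1 rose by 0.39 (SE 0.064, adjusted p = 0.00118) and Txnip by 0.32 (adjusted p = 0.00274), while Ahcy changed by 0.23 (adjusted p = 0.143). Suz12, Ezh1, Eed and Synpo did not pass (adjusted p from 0.133 to 0.904). At other probes Ahcy rose by 0.53 (adjusted p = 0.0282), Synpo fell by 0.41 (adjusted p = 0.0493) and Ifit3 changed by 0.70 (adjusted p = 0.0967). In each of these comparisons the interferon list was higher and the glycolysis list lower by camera. The averaged comparison gave an adjusted p of 0.000701 and 0.000493 (adjusted p = 0.0548 and 0.166 with an estimated correlation). On the same arrays 3 of 6 leukocyte markers rose and 1 fell (3 and 2 adjusted over the list alone), 3 of 5 endothelial markers rose and 2 of 7 mesangial markers rose, these 2 lists with the same counts adjusted over the list alone. The 2 treatments against control gave an adjusted p of 0.00974 and 0.00173 (adjusted p = 0.151 and 0.285 with an estimated correlation). Without a filter on dim probes the interferon median was 0.166 instead of 0.297 for the 2 treatments, and the glycolysis median -0.145 instead of -0.245 for the averaged comparison. The interferon medians with quantile normalization and no background correction were 0.195 and, for the averaged comparison, 0.201 instead of 0.318.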

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

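The tests of the interaction without control replicate 3 and with the glucose effect taken out were chosen only after the result was seen. The response to DZNep differed between the glucose levels, by a test of the difference itself, for Akap9 (0.992), Bod1l (1.61), Hba-a1 (-1.05), Matn4 (-0.754) and Ncapg2 (0.822), each with an adjusted p of 0.0383. Without control replicate 3 the differences were 0.898 to 1.01 times their full size (median 0.923), and none passed, at adjusted p from 0.0593 to 0.0749. As the genes were picked because they passed with that array, its part in these calls stays open. The count was 13 and 12 without control replicates 1 and 2, 1 without high glucose replicate 1 and 0 without any other single array. Of 100 splits of the 12 arrays, which exchanged glucose levels among arrays of the same DZNep status, 2 gave 5 or more genes, the real one included. These splits also move the averaged glucose effect, and the others had a median SE of 0.158 against 0.143 for the real one. That share alone therefore cannot exclude chance. The highest other split gave 24 genes; it exchanges the DZNep arrays with those of both treatments, so that it measures the averaged glucose effect, which also called 24 genes. With that averaged effect taken out beforehand, the highest other of the same 100 splits gave 1 gene. No list passed for the interaction, so 100 of 100 splits gave at least as many, and the highest other gave 4.

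Signal also appeared in probes that carry no single gene symbol and stand outside the comparisons. Of 2962 such detected probes, 799 changed with DZNep, 261 higher and 538 lower. Of these, 16 were above background on 0 control arrays and on every DZNep array.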

How the results depend on the processing

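The setting with a stricter filter and without control replicate 3 was the alternative whose tests were chosen only after the data were seen. Named genes changed with DZNep kept their direction and side of the threshold in 2190 of 2431 alternative values at normal glucose (240 no longer passed) and 1928 of 2156 in high glucose (226). For high glucose against control the numbers were 224 of 396 and 172. Counts for high glucose and for the interaction moved most; the cause was not tested unless the setting itself tests fewer genes or arrays. Requiring at least 1.5-fold left 905 genes (DZNep), 16 (high glucose), 604 (DZNep in high glucose), 766 (both treatments against control), 593 (DZNep averaged) and 6 (high glucose averaged). Array weights gave 50 genes and 1 list for high glucose, 3759 for DZNep in high glucose, 37 for high glucose in DZNep, 27 for the interaction and 50 for high glucose averaged. A trended robust prior gave 318 and 1 list, 24 and 1 list, 167 and 77 for high glucose, high glucose in DZNep, the interaction and high glucose averaged. Quantile normalization without background correction gave 340 and 1 list, 20 and 1 list, 169 and 64 for the same comparisons, and across-gene correlations of 0.71 (DZNep) and -0.153 (glucose). Median centring gave 2242 for DZNep, 6 and 1 list for high glucose, 1480 for DZNep in high glucose, 1904 for both treatments, 3 for the interaction and 11 for high glucose averaged. The authors' values gave 8 and 1 list for high glucose, 0 for the interaction, 2 lists for high glucose averaged, and correlations of 0.57 and 0.0197. Without a filter there were 10 genes and 0 lists for high glucose, 0 genes for the interaction, 0 lists for high glucose averaged, and correlations of 0.593 and -0.00561. A stricter filter gave 84 and 0 lists for high glucose, 13 for the interaction, and correlations of 0.696 and -0.156; without control replicate 3 as well it gave 14 for high glucose and 31 for high glucose in DZNep. Only the arrays compared gave 1 for high glucose and 0 for high glucose in DZNep. Camera with an estimated correlation called 0 lists for DZNep, high glucose, DZNep in high glucose, both treatments, DZNep averaged and high glucose averaged, while fry called 15 (DZNep), 16 (DZNep in high glucose), 2 (high glucose in DZNep), 13 (both treatments) and 20 (DZNep averaged). With the mean of all detected probes Setd7 turned to 0.134 (DZNep), 0.168 (DZNep in high glucose), 0.0997 (both treatments) and 0.151 (DZNep averaged), Adk to -0.00717 (DZNep in high glucose), Srm to -0.00281 (both treatments) and Tyms to 0.00716 (DZNep averaged). With the replicate number as a block the counts were 8 for high glucose, 2 for high glucose in DZNep, 0 for the interaction and 7 for high glucose averaged. Same-numbered arrays deviated together at r from -0.182 to 0.215, 2 of 18 pairs were over 0.1, and 3 of 12 arrays correlated best with their own number, so the numbers were not taken as pairs. Leaving out 1 array gave 2568 to 3448 genes (DZNep), 5 to 70 (high glucose), 1639 to 2754 (DZNep in high glucose), 2 to 16 (high glucose in DZNep), 2138 to 3061 (both treatments), 0 to 13 (interaction), 3758 to 4175 (DZNep averaged) and 6 to 26 (high glucose averaged). Lists ranged over 2 to 2, 0 to 2, 3 to 3, 0 to 1, 2 to 2, 0 to 0, 2 to 3 and 1 to 5 in that order, and the correlations over 0.611 to 0.709 and -0.141 to 0.00237. A slide block was not run, since slides were not used here. Dim genes are limited by their signal over background.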

Other observations

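Tests chosen only after their results were seen were those of other scalings for the interferon, glycolysis and glucose-raised genes, of leukocyte transcripts, of control replicate 3 for the genes high on it, and of splits with the interaction taken out. The response to DZNep of genes raised by high glucose was looked up after their values were seen. Aqp1 changed by 0.10 with DZNep at normal glucose and by -0.01 in high glucose (adjusted p = 0.509 and 0.951). Fgf10 was higher with DZNep at both levels (1.05 and 0.68, adjusted p = 6.06e-06 and 0.000134), and so was Inmt (0.62 and 0.61). In high glucose Slco4a1 was lower with DZNep (-0.98, SE 0.189, adjusted p = 0.00352), where at normal glucose it changed by -0.50 (adjusted p = 0.0609). Endothelin Edn1 was higher by 1.53 with DZNep at both levels. For ribosomal proteins, 14 of 31 Rpl genes were lower with DZNep and 0 higher, and 12 of 26 Rps genes lower and 3 higher, each with an adjusted p of 0.116 over 105 symbol families; 0 families passed.

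Interferon-stimulated genes were higher with DZNep, with a median of 0.318 averaged over glucose and of 0.201 at the lowest under the other scalings, which argues against normalization as the whole cause; without a filter on dim probes it was 0.221, and 0.0443 for DZNep in high glucose. Of 5 abundant leukocyte transcripts, 4 were below background on the DZNep arrays or bounded under the list median (Coro1a -0.187, upper bound 0.213). Against this, 3 of the 6 measured leukocyte markers were higher, Laptm5 (at least 1.72-fold at normal glucose), Csf1r (0.49) and Fcer1g (0.342, adjusted p = 0.0374), and Cd14 was lower (-0.19), so leukocytes stay open. On the same arrays 3 of 5 endothelial markers were higher and 0 lower (median 0.526), and 2 of 7 mesangial and fibroblast markers were higher and 0 lower, so a change in these cell types stays open too. Slides were not tested, and the adjusted p was 0.0548 with an estimated correlation.

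Glycolysis genes were lower with DZNep. The highest median under the other scalings was -0.2 (-0.145 without a filter on dim probes), and of 10000 random lists matched on expression 0 had a median as low as -0.245, which argues against normalization and against a shift of all bright probes. The same markers of other cell types moved on these arrays, so a change in cell types stays open beside a response of the cells. Slides were again not tested, and the adjusted p was 0.166 with an estimated correlation.

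At least 2-fold higher in control replicate 3 than in the other controls were 26 genes, of which 16 had fallen with DZNep, Rbbp7, Ddx5, Hnrnpa2b1 and Gulp1 among them. Without that array the median change of all 26 with DZNep was -0.615 (SE over genes 0.148, where genes are not independent) instead of -0.986, and 21 were below 0, which argues against control replicate 3 as the whole cause, though narrowly. Of the 26, 12 were called lower and 1 higher without it. High glucose against the same controls gave a median of -0.765 (-0.353, SE over genes 0.107, without that array; 0 called in either), and DZNep in high glucose -0.117, so that a raised level in the control group rather than a response to DZNep stays open. At other probes of the 16 genes the median deviation of control replicate 3 was -0.0682 times that at the probe used, but only 6 of the 16 had one and 3 of these deviated upward, so a signal of 1 probe and one of the whole gene cannot be told apart, and no biological explanation was tested.

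An osmotic response was tested as a hypothesis for the genes higher in high glucose, since no osmotic control group was used here. The 9 measured of 14 NFAT5-related genes had a median of 0.0276 with 6 above 0, so that members going both ways leave an osmotic response open: it cannot be told apart from one to glucose. Over Aqp1, Slco4a1, Inmt and Prss35 the lowest value under the other scalings was 0.599. Neighbouring genes of different symbol families rose together with DZNep in 612 of 9797 pairs, against a random mean of 538.6 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give), and fell together in 408 pairs against 332.8; shared regulation of neighbours is a candidate explanation, and overlapping transcripts were not tested.

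Arrays of the groups compared were also split in other ways. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts of genes were 3473 (DZNep), 29 (high glucose), 2487 (DZNep in high glucose), 6 (high glucose in DZNep) and 3090 (both treatments against control), and the highest other split gave 0 genes in each, so 1 split of 10 reached the real count. For lists, the real and highest other numbers were 2 and 1, 2 and 0, 3 and 3, 0 and 1, and 2 and 2 in that order. Over 100 splits of the 12 arrays, only the real one reached the 4295 genes of DZNep averaged over glucose (highest other 5). There DZNep was exchanged among arrays of the same glucose level. The other splits left DZNep effects in the spread (median SE 0.105 against 0.0713), which can lower their counts. Chance in how these arrays were grouped can be excluded for that count as a whole. This covers no single gene and no difference between cultures or slides. For high glucose averaged over DZNep, glucose was exchanged among arrays of the same DZNep status. There only the real split reached the 24 genes (highest other 2) and the 4 lists (highest other 2). Chance in how these arrays were grouped can be excluded for the count of 24 genes. With the interaction taken out beforehand the highest other gave 2 genes and 6 lists, and 2 of 100 splits reached 4 lists; with an estimated correlation 0 lists passed. For the 4 lists no verdict on chance is drawn, since their number depended on these settings. Chance cannot be excluded for the 2 lists of DZNep averaged over glucose, which 16 of 100 splits reached (highest other 3).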
